A study of Mus musculus with 20 samples.

How the data were processed

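RNA was sequenced from cultures of mouse articular chondrocytes, the cells that build and maintain the cartilage of joints. Per the labels, the cells came from 6-week-old mice and were kept for 48 hours with vehicle (DMSO), 20 µM 25-hydroxycholesterol (25HC), 20 µM 25-hydroxycholesterol-3-sulfate (25HC3S) or 2 µM GW3965, with 5 libraries in each of the 4 groups and 20 in all. Nothing in the labels says whether the 5 libraries of a group came from separate animals, cultures or wells, so the p-values measure the spread between these libraries, which may be partly technical.

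The authors deposited one table of FPKM (fragments per kilobase of gene, scaled to the depth of the library) with gene coordinates and gene lengths for 54532 genes. Per the labels' protocols, RNA was taken with Trizol and libraries were made with a rapid RNA-seq kit. Per the submitters' processing notes, CASAVA 1.8 and HISAT2 2.0.5 were used. The program that counted fragments, its strand setting and the genome build are not given in the sources used here. Of the gene identifiers, 99.93% were found in GENCODE release M21, and 98.26% of those had the same chromosome, start and end as in that release, which is on build GRCm38. Coordinates are given as the file has them. Genes of families with near-identical copies or with overlapping neighbours (Serpina3g, Slfn9, Ifit1, Scd1 and Scd2 among those named) are uncertain to the extent that the counting could split or share their fragments.

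The depth of each library was worked out from the deposited FPKM: each value times its gene length was a whole multiple of one step per library, within 0.02 of a whole number for 100% of values. The libraries held 14653777 to 19365220 fragments in genes. The sums of FPKM times gene length were not equal between libraries, so the total the authors divided by carries a factor per library of 0.930 to 1.045. With fragments from PCR and no molecular identifiers known, fragments are not independent molecules, and depth describes counting error only.

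FPKM values are not counts, so the tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). A fold change is therefore on the log2(FPKM + 1) scale, which understates the change of genes with low values. Genes with FPKM of at least 1 in at least 5 of the 20 libraries were tested, 12752 in all. One mean per group was fitted over all 20 libraries, so that the groups share one estimate of the spread, with empirical Bayes moderation along a trend. The spread was not equal between groups. The chi-square per gene of 2 libraries of a group, their difference set against sampling noise, reached 194 in Vehicle and 84.7 in 25HC3S. It reached 7.80 in 25HC and 6.60 in GW3965. The standard errors therefore tend to be too small in comparisons with Vehicle and too large for 25HC with GW3965. A fit of only the 2 groups compared gave fewer calls in the former and more in the latter. Each of the 6 differences between 2 groups was tested two-sided, and p was adjusted by Benjamini-Hochberg within a comparison. A gene was called at an adjusted p under 0.05. Errors of log2 differences are the standard errors of that model, intervals are 95% intervals, and group means of FPKM are given with their SD over 5 libraries. The same steps were tested on simulated data for 25HC against Vehicle, with 200 of 12752 genes changed. There 150 genes were called, 8 of them false. Of 50 genes changed at each fold, 21 were found at a fold of 1.5, 38 at 2, 47 at 4 and 36 at 0.5. For 25HC3S with Vehicle in the same simulated set, where no gene was changed, 0 were called. These data were drawn gene by gene, without deviations that the genes of a library share, so this test does not cover false calls from such deviations. Simulated unchanged groups that keep them, made of libraries drawn with replacement and given with the results, reached up to 5792 calls for 25HC with Vehicle.

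The 26 gene lists were fixed before the data were examined. They cover LXR target genes, cholesterol biosynthesis enzymes, sterol uptake and SREBP feedback genes, fatty acid synthesis and desaturation, oxysterol metabolism and receptors, PPAR target genes, cartilage matrix and chondrocyte genes, cartilage catabolic genes, chondrocyte hypertrophy, dedifferentiation and fibroblast genes, inflammatory mediators, interferon-stimulated genes, the integrated stress response, the unfolded protein response, NRF2 target genes, proliferation, p53 target genes, Hedgehog target genes, lysosome and autophagy, and markers of macrophages, endothelium, skeletal muscle, adipocytes, osteoblasts and osteocytes, erythroid cells and neutrophils, and synovial lining and tendon. Some genes stand in more than one list. Lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. An adjusted p of a list is from the preset correlation unless the sentence says otherwise, and the median of a list is over its measured members.

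Genes to be named were also fixed by rule before the data were examined: the 10 largest rises and 10 largest falls of each comparison with Vehicle and of 25HC3S with 25HC, and 5 and 5 of the other comparisons, among called protein-coding genes with a symbol that is not a predicted or clone name, whose libraries did not overlap between the groups, with a mean FPKM of at least 1 in the higher group; up to 4 members of each list with the smallest p; and 16 genes of oxysterol and cartilage biology in every comparison. Other members of a list that are named were chosen after their values were seen. Some genes that these rules name are not reported here. Sult2b1, one of the 16, was below the filter on low values and was not tested.

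The alternatives tried were a pseudocount of 0.1, no filter, a filter at FPKM of at least 5, rescaling to TPM, median-of-ratios scaling, moderation without the trend or robust, a fit of only the 2 groups compared, library weights, the replicate number as a block, leaving out each replicate, and limma voom on the recovered fragments. One alternative was added after seeing the data: leaving out 4 libraries of low complexity, described with the results. A library was put among these when it had fewer than 75% of the median number of genes with exactly 1 fragment. No pair of libraries had identical values, and every pair within a group differed by more than sampling noise, with a chi-square per gene of at least 2.69. Separate preparations of one RNA would differ by more than that noise too, so this does not show that the libraries are independent. Each library was entered as 1 replicate. Figures were drawn with matplotlib in Python.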

Results

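The series measured which genes mouse articular chondrocytes expressed after 48 hours with an oxysterol, its sulfate or a synthetic agonist of the liver X receptors. 25HC is an oxidised cholesterol made by the enzyme Ch25h, and 25HC3S carries a sulfate at the 3 position of the same sterol. Oxysterols of this kind are known to act on the liver X receptors (LXR, encoded by Nr1h3 and Nr1h2) and to hold back SREBP2, the transcription factor that drives cholesterol synthesis. GW3965 is a non-steroidal LXR agonist. Each group held 5 libraries with 14653777 to 19365220 fragments in genes, and 12752 genes were tested.

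The cells expressed cartilage genes at high levels. Col2a1, the main collagen of cartilage, had a mean of 1958 FPKM ± 996 (SD, n = 5) in Vehicle. Of the genes that make and sense 25HC, Ch25h had 6.55 FPKM ± 3.55 in Vehicle, Cyp7b1, which hydroxylates 25HC, had 2.24 ± 1.22, Nr1h2 had 14.8 ± 4.49, Nr1h3 had 2.51 ± 0.887 and Rora had 5.43 ± 2.58. Sult2b1, a sulfotransferase for sterols, was at most 0.186 FPKM in any library. Macrophage genes were present too, with Cd68 at 64.9 FPKM ± 27.6 in Vehicle.

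In 4 libraries far fewer genes had exactly 1 fragment than in the other 16. The number was 237 to 1171 in Vehicle replicates 2, 3 and 4 and 25HC3S replicate 1, against 1808 to 2057 in the others, and 16346 to 19648 genes were detected against 20847 to 21607. In Vehicle replicates 3 and 4 and 25HC3S replicate 1, mitochondrial genes took 4.07%, 3.60% and 3.14% of fragments, against 0.888% to 1.41% in the 16, while Vehicle replicate 2 had 0.369%. Mki67, a gene of dividing cells, had 43.0, 42.9 and 36.3 FPKM in those 3 libraries and 10.0 to 19.6 in the 16, and the first principal component, with 49.2% of the variance, set the 3 apart. The list of 20 proliferation genes did not go with Mki67. Its median log2 difference in the 3 was -0.16, -0.20 and -0.20 relative to the libraries of the same group outside the 4. Because 3 of the 5 Vehicle libraries are among the 4, every comparison with Vehicle carries their values. All comparisons carry the spread of the 4 libraries, since the groups share one estimate of it. The counts of called genes of each comparison are given with and without the 4 libraries, an alternative chosen after seeing the data. The comparisons without them rest on Vehicle replicates 1 and 5.

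**Figure D1:**
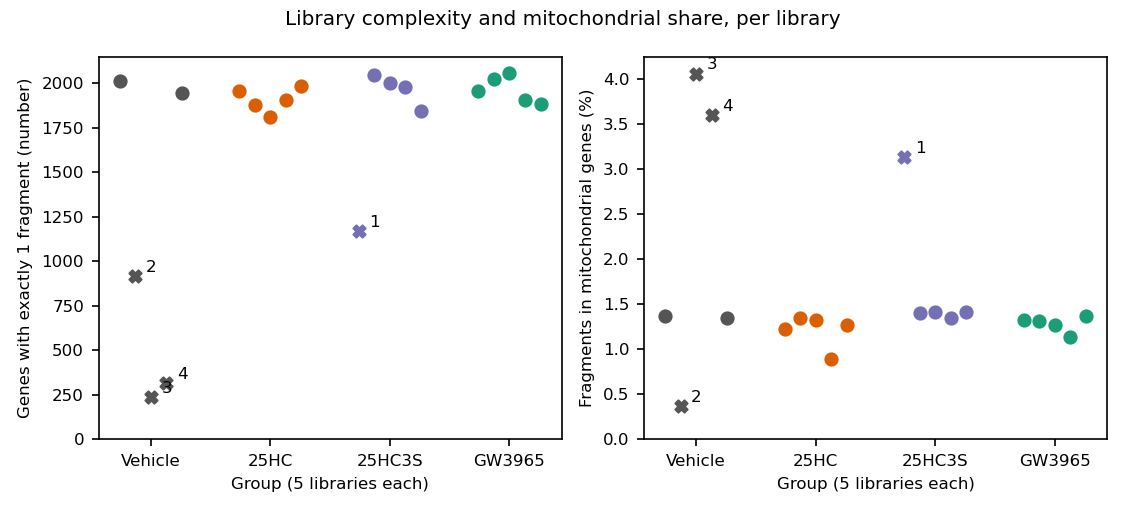
Genes with exactly 1 fragment (left, number) and the share of fragments in mitochondrial genes (right, %) in each of the 20 libraries, by group. Crosses with a replicate number mark the 4 libraries with few such genes, 237 to 1171 against 1808 to 2057 in the others, and dots mark the other 16.

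The comparison of 25HC with Vehicle asks what the free oxysterol does to these cells. With 25HC, few genes were called, among them Sqle and Srebf2 of the sterol pathway as higher and a cholesterol exporter as lower. Sqle, an enzyme of cholesterol synthesis, rose from 11.6 FPKM ± 1.04 to 16.1 ± 1.15 (SD, n = 5 each), a log2 difference of 0.44 ± 0.07 (SE), and Srebf2, which encodes SREBP2, by 0.32 ± 0.06. Abca1, an LXR target that exports cholesterol, fell from 11.2 FPKM ± 2.66 to 5.96 ± 0.482, by a log2 difference of -0.79 ± 0.13. Tmem246 rose by 0.47 ± 0.07.

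In all, 5 genes were called, 4 higher and 1 lower, with adjusted p up to 0.049 (Srebf2), and 3863 genes had an unadjusted p under 0.05. Of 19 measured cholesterol biosynthesis enzymes, 1 rose, 0 fell and 18 did not pass, while 11 rose when adjusted over the list alone. 17 of the 19 had a positive difference, with a median of 0.27 and an adjusted p of 6.1e-06, but adjusted p = 0.15 with an estimated correlation. Of 8 sterol uptake and SREBP feedback genes 2 rose, and 3 when adjusted over the list alone (adjusted p = 0.015 for the list, and adjusted p = 0.26 with an estimated correlation). When the 4 libraries were left out, both lists had an adjusted p of 0.033 with an estimated correlation.

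Of 12 measured LXR target genes, Abca1 fell, 0 rose and 11 did not pass, and adjusted over the list alone 2 rose and 2 fell. Abcg1, which exports cholesterol to HDL, had a log2 difference of -0.22 ± 0.12, and Srebf1, the LXR target that drives fatty acid synthesis, had 0.35 ± 0.12. Other lists had a positive median and a call that was lost with an estimated correlation: chondrocyte hypertrophy (median 0.20, adjusted p = 0.013, then adjusted p = 0.26 with an estimated correlation), lysosome and autophagy (0.19, adjusted p = 0.013, then adjusted p = 0.48) and osteoblast and osteocyte markers (0.41, adjusted p = 0.013, then adjusted p = 0.26), and the integrated stress response had 0.45 (adjusted p = 0.047, then adjusted p = 0.55). Vehicle replicates 3 and 4, the libraries that stand apart, were low for all 4 lists relative to Vehicle replicates 1 and 5, with medians of -0.33 and -0.46 for chondrocyte hypertrophy, -0.24 and -0.33 for lysosome and autophagy, -0.70 and -0.40 for osteoblast and osteocyte markers and -0.98 and -0.87 for the integrated stress response. The medians of these lists without the 4 libraries were 0.07, 0.01, 0.11 and 0.04. None of the matrix and protease genes fixed for every comparison passed: the log2 difference was 0.38 ± 0.23 for Col2a1, 0.20 ± 0.09 for Acan, -0.29 ± 0.19 for Mmp3, 0.19 ± 0.08 for Mmp13 and -0.33 ± 0.17 for Adamts5. When the 4 libraries were left out, 2 genes were higher and 1 lower, and 1 of the 5 called genes was called again, Abca1 (-0.46 ± 0.06, adjusted p = 0.019). The calls of Sqle (0.39 ± 0.07, adjusted p = 0.051), Srebf2 (0.29 ± 0.05, adjusted p = 0.078) and Tmem246 (0.37 ± 0.07, adjusted p = 0.14) ended with the same direction. Without Vehicle replicate 1 the counts were 1445 higher and 1214 lower, and without Vehicle replicate 5 they were 1148 and 937, where in both cases 3 of the 4 Vehicle libraries left have few genes at exactly 1 fragment. Leaving out 1 library ended the call of Abca1 in 7 fits (without Vehicle replicate 2, 3 or 4 or 25HC replicate 1, 2, 3 or 5, adjusted p up to 0.0948), of Srebf2 in 7 (without Vehicle replicate 2 or 4 or any 25HC library, up to 0.221), of Tmem246 in 3 (without 25HC replicate 1, 2 or 3, up to 0.0874) and of Sqle in 1 (without 25HC replicate 3, 0.0874).

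The comparison of 25HC3S with Vehicle asks the same of the sulfated oxysterol. Cells given 25HC3S had less mRNA of cholesterol synthesis genes, and their macrophage genes changed in both directions. Msmo1 (-1.10 ± 0.13), Idi1 (-1.05 ± 0.14), Cyp51 (-0.89 ± 0.08) and Insig1 (-0.91 ± 0.11), enzymes of sterol synthesis and a regulator that retains SREBP in the endoplasmic reticulum, were among the 10 largest falls. Mrc1, the mannose receptor of macrophages, fell from 25.2 FPKM ± 5.37 to 6.40 ± 0.523, a log2 difference of -1.80 ± 0.13. Mmp12, a metalloelastase made mainly by macrophages, rose from 1.62 FPKM ± 0.222 to 4.39 ± 0.42, a difference of 1.04 ± 0.08.

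In all, 59 genes were higher and 146 lower, of which 7 and 8 changed at least 2-fold. Of 19 cholesterol biosynthesis enzymes 11 fell, 0 rose and 8 did not pass, and 13 fell when adjusted over the list alone. Their median was -0.47, with an adjusted p of 8.9e-20 and 0.00069 with an estimated correlation. Besides those above, Sqle (-0.71 ± 0.07) and Hmgcs1 (-0.88 ± 0.1) fell. Of 8 sterol uptake and SREBP feedback genes 4 fell (5 adjusted over the list alone), among them Insig1, Stard4 (-0.74) and Srebf2 (-0.33 ± 0.06), with an adjusted p of 5e-05 and 0.021 with an estimated correlation, which became adjusted p = 0.064 without the 4 libraries. Of 17 genes of fatty acid synthesis and desaturation 4 fell, 6 adjusted over the list alone: Scd1 (-0.92 ± 0.17), a desaturase, Fads2 (-0.54), Acsl3 (-0.44) and Acly (-0.25). That list's adjusted p of 4e-05 became adjusted p = 0.17 with an estimated correlation. Of 12 LXR target genes 0 rose and 0 fell, and 1 rose when adjusted over the list alone. Abcg1 had a difference of 0.48 ± 0.12 (adjusted p = 0.055), Abca1 -0.21 ± 0.13 and Srebf1 0.04 ± 0.12. Without the 4 libraries 1 of the 12 rose, Abcg1 (0.37 ± 0.08, adjusted p = 0.019).

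Of 14 macrophage markers 2 fell, 1 rose and 11 did not pass, and adjusted over the list alone 3 fell and 1 rose. Mrc1 and Adgre1 (F4/80, -0.83 ± 0.09) fell and Cd14, a co-receptor for lipopolysaccharide, rose by 0.75 ± 0.11. The list's median was -0.25 (adjusted p = 0.0057, then adjusted p = 0.34 with an estimated correlation). Vehicle replicates 3 and 4 were low for this list too, at -0.47 and -0.66 relative to Vehicle replicates 1 and 5, and without the 4 libraries 8 of the 14 fell and 1 rose, with a median of -0.63 (adjusted p = 0.14 with an estimated correlation). Cd68 ran from 16.2 to 81.4 FPKM among the Vehicle libraries, with 16.2 in Vehicle replicate 2. Other large falls of genes known from macrophages were Fcrls (-1.72 ± 0.13), Stab1 (-1.22 ± 0.08) and Siglec1 (-1.03 ± 0.12), and other large rises were Trem1 (0.75 ± 0.12) and Clec4e (0.49 ± 0.08), receptors of activated myeloid cells. Car3, a carbonic anhydrase, fell by 1.54 on the log2 scale. Plau, which encodes urokinase, fell by 0.82. Rnf145, a ubiquitin ligase of the sterol pathway, rose by 0.64 ± 0.05. Serpina3g (0.62 ± 0.13), Avpr1a (0.55 ± 0.13), Spn (0.54 ± 0.11) and Gldn (0.53 ± 0.09) were also among the 10 largest rises.

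Of 15 cartilage catabolic genes 2 rose, Mmp12 and Ptgs2 (0.48), the inducible cyclooxygenase, and 2 fell, Plau and Adamts1 (-0.31), with 11 not passing and 4 rising and 2 falling when adjusted over the list alone. Mmp13 (0.30 ± 0.08, adjusted p = 0.055), Mmp3 (-0.18 ± 0.19), Adamts5 (-0.11 ± 0.17), Col2a1 (0.16 ± 0.23) and Acan (-0.14 ± 0.09) did not pass. Of 14 dedifferentiation and fibroblast genes 1 fell, Postn (-0.46), a matricellular protein gene, and 5 fell when adjusted over the list alone (list adjusted p = 0.0038, and 0.021 with an estimated correlation). Single genes of 4 further lists fell: Gpr183 (-0.66), the receptor for dihydroxycholesterols, Ifit1 (-0.92), induced by interferon, Sesn1 (-0.48), a p53 target, and Gpnmb (-0.26), a lysosomal gene. Of the 14 interferon-stimulated genes 4 fell when adjusted over the list alone (median -0.26, adjusted p = 0.0023, then adjusted p = 0.31 with an estimated correlation), and 6 fell without the 4 libraries (median -0.50, adjusted p = 0.097 with an estimated correlation). Without the 4 libraries 169 genes were higher and 335 lower, and 146 of the 205 called genes were called again, all in the same direction. Members of lists called lower there were 15 of the 19 cholesterol biosynthesis enzymes, 5 of the 8 sterol uptake and SREBP feedback genes, 2 of 21 cartilage matrix and chondrocyte genes, 3 of 17 lysosome and autophagy genes and 2 of the 14 dedifferentiation and fibroblast genes, where 1 other was higher. Of the genes named here as called, Spn (0.41 ± 0.14, adjusted p = 0.13) and Serpina3g (0.58 ± 0.19, adjusted p = 0.11) lost their calls there, and the falls of Stard4 (-0.43 ± 0.07), Plau (-0.49 ± 0.12) and Acsl3 (-0.25 ± 0.06) were more than 1.5 times smaller. Without Vehicle replicate 1 the counts were 339 and 283, and without 25HC3S replicate 2 they were 24 and 74. Leaving out 1 library of Vehicle or 25HC3S ended, in 2 to 7 fits each, the calls of Acly, Ifit1, Avpr1a, Adamts1, Serpina3g, Fads2 and Spn, with the same direction and adjusted p up to 0.126 (Acly, without 25HC3S replicate 2).

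**Figure D2:**
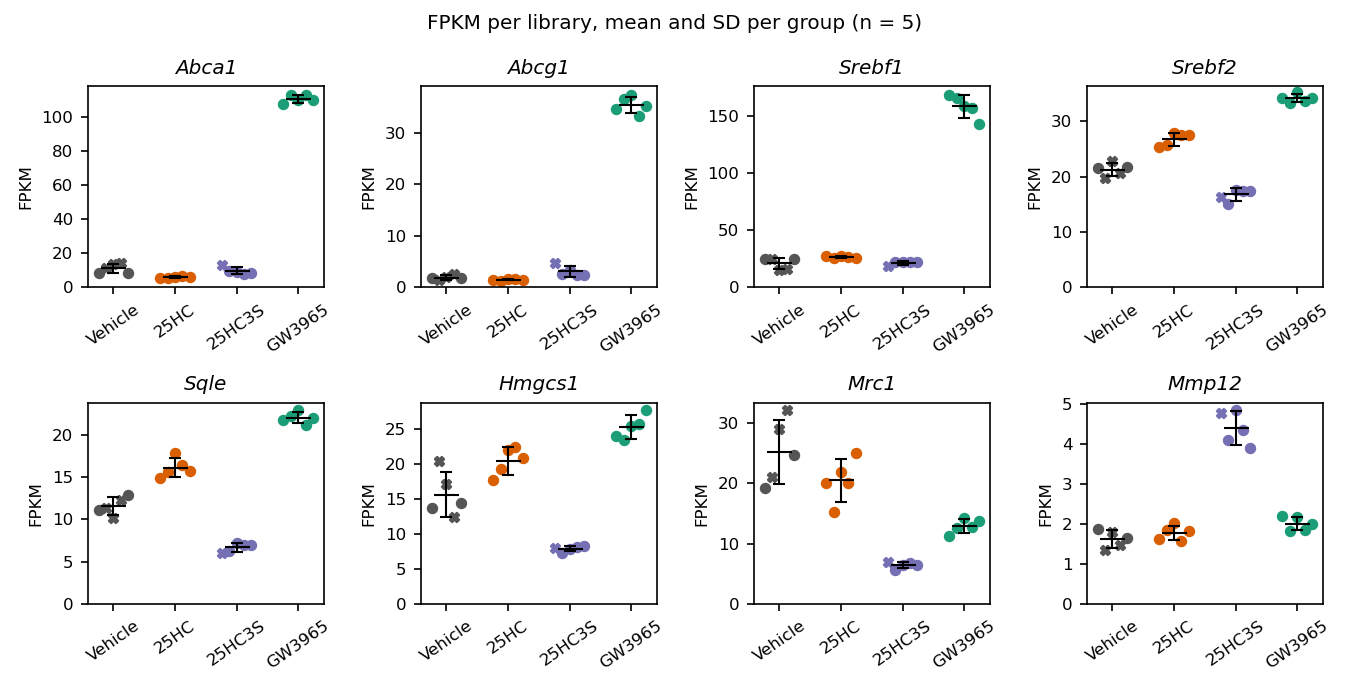
FPKM of 8 genes in each library (dots; crosses are the 4 libraries with few genes at 1 fragment), by group, with the group mean and SD in black (n = 5) and a separate axis from 0 for each gene. Srebf2 and Sqle lie higher in 25HC and lower in 25HC3S than in Vehicle, and Abca1 averages 111 FPKM in GW3965 against 11.2 in Vehicle.

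The comparison of GW3965 with Vehicle shows the response to a direct LXR agonist. LXR target genes and the genes of cholesterol and fatty acid synthesis rose together, and genes of cell division fell. Abcg1 rose from 1.88 FPKM ± 0.40 to 35.4 ± 1.61 (3.67 ± 0.12 on the log2 scale), Abca1 from 11.2 to 111 FPKM ± 2.1 (3.22 ± 0.13) and Srebf1 from 21.1 ± 4.99 to 159 ± 10.3 (2.88 ± 0.12). Scd2 (2.48 ± 0.07), Scd1 (2.52 ± 0.17) and Fads2 (2.25 ± 0.12), fatty acid desaturases, rose by similar amounts. Top2a (-1.06 ± 0.15) and Mki67 (-1.05 ± 0.27), genes of dividing cells, fell.

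In all, 445 genes were higher and 379 lower, 48 and 11 of them by at least 2-fold. Of 12 LXR target genes 9 rose and 0 fell, also when adjusted over the list alone. Lpcat3 (1.64), a phospholipid acyltransferase, Mylip (1.28), a ubiquitin ligase, and Nr1h3 itself (0.44 ± 0.13) were among them. Apoe, a lipoprotein gene, rose by 2.57 ± 0.60. Of 19 cholesterol biosynthesis enzymes 18 rose (19 adjusted over the list alone), with a median of 0.81: Lss by 0.98, Cyp51 by 0.93, Sqle by 0.88 and Dhcr7 by 0.85. Mvd rose by 1.69 ± 0.31. Of 8 sterol uptake and SREBP feedback genes 5 rose (6 adjusted over the list alone), Insig1 by 1.89 ± 0.11 and Srebf2 by 0.66 among them. Of 17 genes of fatty acid synthesis and desaturation 11 rose (16 adjusted over the list alone), with Fasn, fatty acid synthase, up by 1.61, Acsl3 by 1.37 and Mid1ip1 by 1.67 ± 0.19. With an estimated correlation these 4 lists had adjusted p of 2.9e-06, 7.3e-05, 0.0018 and 0.0013.

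Of 20 proliferation genes 11 fell, 0 rose and 9 did not pass, and 14 fell when adjusted over the list alone (median -0.43, adjusted p = 1.6e-13, and 0.0053 with an estimated correlation). Mcm7 (-0.64), Mcm6 (-0.66), Mcm5 (-0.58) and Mcm4 (-0.50), subunits of the replicative helicase, fell, and so did Ncapg2 (-1.04 ± 0.16), Cenpf (-0.98 ± 0.22) and Diaph3 (-0.95 ± 0.15). Mki67 was high in Vehicle replicates 3 and 4, the libraries that stand apart, while the median of the proliferation list there was -0.16 and -0.20 relative to Vehicle replicates 1 and 5. Without the 4 libraries the fall of Mki67 was -0.57 ± 0.10, that of Top2a -0.67 ± 0.09 and that of Cenpf -0.39 ± 0.11 (adjusted p = 0.05). In that fit 19 of the 20 proliferation genes fell, and the list's median was -0.53. Of 14 interferon-stimulated genes 5 fell (6 adjusted over the list alone), Ifit1 (-1.26), Ifi44 (-0.61) and Oasl2 (-0.59) among them, with an adjusted p of 0.0023 and adjusted p = 0.3 with an estimated correlation, and 8 fell without the 4 libraries. Slfn9 (-1.24 ± 0.23), a gene of the Schlafen family, fell too. Of 18 genes of the integrated stress response 5 rose (11 adjusted over the list alone), among them Fgf21 (1.45) and Atf3 (0.94); the list's adjusted p of 0.00063 became adjusted p = 0.16 with an estimated correlation. Its median of 0.58 was 0.17 without the 4 libraries, of which Vehicle replicates 3 and 4 were low for it as given above, and 6 genes of it were called there. 4 of 14 NRF2 target genes rose, 7 and 1 falling when adjusted over the list alone, with Hmox1, haem oxygenase, up by 0.78 (adjusted p = 0.017 for the list, then adjusted p = 0.057 with an estimated correlation). 5 of 17 genes of lysosome and autophagy rose (8 adjusted over the list alone), Ctsd by 0.97 and Sqstm1 by 0.42 (adjusted p = 0.00063, then adjusted p = 0.22), and the median of 0.20 was 0.06 without the 4 libraries. 3 of 11 PPAR target genes rose (5 adjusted over the list alone), Plin2 of the lipid droplet coat by 0.61, Angptl4 by 1.39 and Ucp2 by 0.96 (adjusted p = 0.026, then adjusted p = 0.057). With the 4 libraries left out, the adjusted p with an estimated correlation passed for the interferon (0.049), stress response (0.048), NRF2 (0.048) and PPAR (0.0074) lists, and for lysosome and autophagy it was adjusted p = 0.065. The p53 target genes, of which 2 of 12 rose with all 20 libraries and 6 without the 4, had adjusted p = 0.22 and then 0.048, both with an estimated correlation.

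Of the cartilage genes, Mmp3, stromelysin, fell from 15.3 FPKM ± 5.56 to 6.54 ± 1.1 (-1.07 ± 0.19, adjusted p = 0.0021), the 1 called member of 15 cartilage catabolic genes, of which 3 rose and 2 fell without the 4 libraries. Col2a1 had 0.72 ± 0.23 (adjusted p = 0.065), Acan -0.14 ± 0.09, Mmp13 -0.07 ± 0.08 and Adamts5 -0.05 ± 0.17. Car3 (-1.47 ± 0.17) and Pi15 (-1.08 ± 0.20) fell. Cyp7b1 fell by 0.70, the 1 called of 10 genes of oxysterol metabolism and receptors. Vegfa (0.96), Acta2 (0.46), Cdkn1a (0.49) and Gdf15 (1.56) rose, and Vcam1 (-0.51) fell. Of the macrophage markers Mrc1 (-0.89 ± 0.13) and Adgre1 (-0.32) fell, and 4 rose and 2 fell when adjusted over the list alone. With the 4 libraries left out, 508 genes were higher and 483 lower, and 477 of the 824 called genes were called again. There the rises of Apoe (1.16 ± 0.08), Mvd (1.01 ± 0.12), Angptl4 (0.70 ± 0.07), Gdf15 (0.57 ± 0.09), Vegfa (0.47 ± 0.06), Ctsd (0.41 ± 0.05), Hmox1 (0.32 ± 0.05) and Cdkn1a (0.24 ± 0.06) and the falls of Slfn9 (-0.78 ± 0.08), Pi15 (-0.60 ± 0.10), Diaph3 (-0.58 ± 0.12) and Ncapg2 (-0.56 ± 0.07) were more than 1.5 times smaller, as were those of Mki67 and Top2a given above. Col2a1 (0.49 ± 0.09, adjusted p = 0.0018) and Adamts5 (0.31 ± 0.08, adjusted p = 0.02) were called there as higher. Calls were lost with a smaller fold by Cenpf as given above, Ucp2 (0.24 ± 0.10), Fgf21 (0.78 ± 0.24), Cyp7b1 (-0.32 ± 0.13), Nr1h3 (0.10 ± 0.07) and Acta2 (0.32 ± 0.13), and by Adgre1 with about the same fold (-0.34 ± 0.11). Without Vehicle replicate 1 the counts were 1820 and 1427, and without GW3965 replicate 1 they were 233 and 221. Leaving out 1 library of Vehicle or GW3965 ended, in 5 to 7 fits each, the calls of Nr1h3, Mki67, Vegfa, Adgre1, Ucp2 and Cyp7b1, with adjusted p up to 0.109 (Nr1h3, without Vehicle replicate 3).

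25HC3S differs from 25HC by the sulfate on carbon 3, and both were given at 20 µM for 48 hours, so that their difference was tested directly. Genes of cholesterol synthesis were lower with the sulfate, and the cholesterol exporters were higher. Sqle averaged 6.69 FPKM ± 0.517 with 25HC3S and 16.1 ± 1.15 with 25HC (-1.15 ± 0.07). Abcg1 was higher with 25HC3S by 0.70 ± 0.12 and Abca1 by 0.58 ± 0.13. Fcrls (-1.83 ± 0.13), Mrc1 (-1.52 ± 0.13) and Stab1 (-1.29 ± 0.08) were lower, and Mmp12 (0.96 ± 0.08) and Cd14 (0.70 ± 0.11) higher.

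With 25HC3S 20 genes were higher and 84 lower than with 25HC, 3 and 13 by at least 2-fold. Of 19 cholesterol biosynthesis enzymes 14 were lower and 0 higher (17 lower adjusted over the list alone), with a median of -0.72, an adjusted p of 1.7e-57 and 7.4e-07 with an estimated correlation. Hmgcs1 (-1.26 ± 0.10), Msmo1 (-1.17 ± 0.13), Cyp51 (-1.17 ± 0.08) and Fdft1 (-1.10 ± 0.11) were among them. Insig1 (-1.41 ± 0.11) and Srebf2 (-0.65 ± 0.06) were 2 of the 4 called of 8 sterol uptake and SREBP feedback genes, of which 4 were also lower when adjusted over the list alone (adjusted p = 0.00012 with an estimated correlation). Of 17 fatty acid genes 4 were lower (6 adjusted over the list alone), Scd2 by -0.49 and Fads2 by -0.62 among them (adjusted p = 0.042 with an estimated correlation). Of 12 LXR target genes Abcg1 and Abca1 were higher and 0 lower, also when adjusted over the list alone, and the list was not called (adjusted p = 0.48). Srebf1 had a difference of -0.30 ± 0.12 with a 95% interval from -0.55 to -0.06, and did not pass, but was called lower without the 4 libraries (-0.25 ± 0.04, adjusted p = 0.0013). Rnf145 (0.59 ± 0.05), Nrcam (0.55 ± 0.12), Trem1 (0.53 ± 0.12), Clec5a (0.47 ± 0.11) and Ckap2 (0.39 ± 0.09) were also higher.

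Of 14 macrophage markers Mrc1 and Adgre1 (-0.67) were lower and Cd14 higher, and 9 were lower and 1 higher when adjusted over the list alone (median -0.63, adjusted p = 6.2e-10, and 0.042 with an estimated correlation, which became adjusted p = 0.15 without the 4 libraries). Of 21 cartilage matrix and chondrocyte genes 1 was lower, Cilp (-0.55), a matrix protein of the middle zone of cartilage, and 2 adjusted over the list alone; the median was -0.34, with an adjusted p of 3.4e-07 and adjusted p = 0.068 with an estimated correlation. Acan (-0.34, 95% interval -0.52 to -0.16) and Col2a1 (-0.21, interval -0.70 to 0.27) did not pass, and without the 4 libraries Acan was called lower (-0.38 ± 0.07, adjusted p = 0.0027). Of 14 dedifferentiation and fibroblast genes 2 were lower, Postn by -0.41 and Lum by -0.28, and 5 adjusted over the list alone (adjusted p = 0.0012 with an estimated correlation). Interferon-stimulated genes had a median of -0.39 with 0 of 14 called, 2 lower when adjusted over the list alone, and an adjusted p of 5.5e-07 that became adjusted p = 0.068 with an estimated correlation. For Mmp3 the difference was 0.11 (interval -0.30 to 0.51) and for Mmp13 0.11 (interval -0.05 to 0.27), so that the data set bounds on a difference between the compounds without showing that they act alike. Leaving out the 4 libraries, 317 genes were higher and 599 lower, and all 104 called genes were called again in the same direction. Called lower there were 18 of the 19 cholesterol biosynthesis enzymes, 9 of the 17 fatty acid genes, 2 of the 12 LXR target genes (2 were higher), 9 of the 14 macrophage markers (1 was higher), 8 of the 21 cartilage matrix and chondrocyte genes, 6 of the 14 dedifferentiation and fibroblast genes (1 was higher), 5 of the 14 interferon-stimulated genes (adjusted p = 0.15 for the list with an estimated correlation) and 6 of 17 lysosome and autophagy genes. The 25HC3S group holds 1 of the 4 libraries and 25HC 0. Leaving out 1 library of either group left 5 to 11 genes higher and ended, in 6 to 10 fits each, the calls of Clec5a, Lum, Abca1, Trem1, Ckap2, Nrcam and Cilp, with adjusted p up to 0.166 (Clec5a, without 25HC replicate 4).

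**Figure D3:**
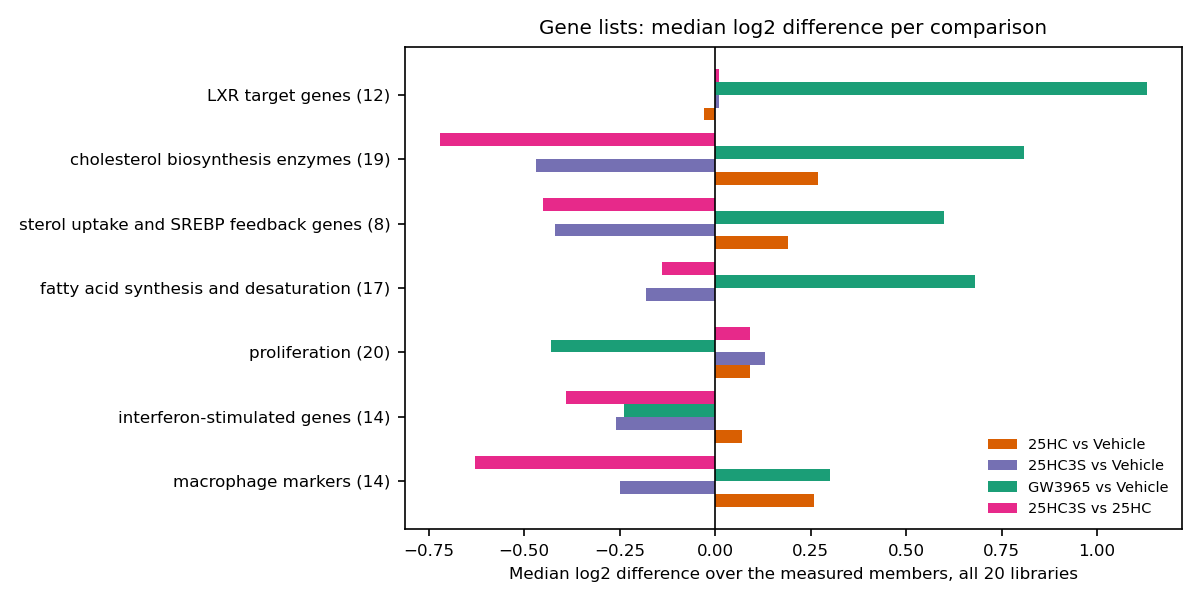
Median log2 difference over the measured members (their number in brackets) of 7 gene lists in 4 comparisons, fitted on all 20 libraries. The cholesterol enzymes have medians of 0.27 in 25HC, -0.47 in 25HC3S and 0.81 in GW3965 against Vehicle, and the LXR targets 1.13 in GW3965 against -0.03 and 0.01 in the oxysterols.

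GW3965 was given at 2 µM and the oxysterols at 20 µM, so these comparisons set compounds side by side at different doses. Both oxysterols left LXR targets and lipid synthesis genes far below their levels with GW3965. Abca1 was lower by a log2 difference of -4.01 ± 0.13 with 25HC and -3.42 ± 0.13 with 25HC3S, Abcg1 by -3.89 ± 0.12 and -3.19 ± 0.12, Srebf1 by -2.54 ± 0.12 and -2.84 ± 0.12, and Scd1 by -2.99 ± 0.17 and -3.44 ± 0.17. Proliferation genes were higher with both than with GW3965: 12 of 20 with 25HC, where Mcm5 differed by 0.66 and Mcm4 by 0.49, and 15 of 20 with 25HC3S, where they differed by 0.72 and 0.59. Adjusted over the list alone the numbers were 19 and 18, and with an estimated correlation the adjusted p were 1.3e-05 and 7.5e-05.

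Against GW3965, 114 genes were higher and 108 lower with 25HC, and 271 higher and 320 lower with 25HC3S. Of the 12 LXR target genes 6 were lower with each, and 7 and 11 adjusted over the list alone. Of 19 cholesterol biosynthesis enzymes 13 were lower with 25HC (17 adjusted over the list alone) and 18 with 25HC3S (19 adjusted over the list alone), with medians of -0.57 and -1.45. Sqle was lower by -0.43 and -1.59. Of 17 fatty acid genes 14 were lower with each compound, and 15 with each adjusted over the list alone, among them Scd2 with 25HC (-2.25 ± 0.07). Insig1 was lower with 25HC3S by -2.80 ± 0.11. With 25HC, Car3 (0.98 ± 0.17), Ifit1 (0.87 ± 0.21), Cxcl10 (0.87 ± 0.21), a chemokine induced by interferon, Pbk (0.81 ± 0.16) and Mmp3 (0.78 ± 0.19) were the largest rises. With 25HC3S they were Tcf19 (1.03 ± 0.22), Cxcl10 (1.01 ± 0.21), Slfn9 (1.01 ± 0.23), Top2a (1.01 ± 0.15) and Ncapg2 (1.01 ± 0.16), and Mmp3 (0.89) and Mmp13 (0.37) were higher too. The calls of Mmp3, Ifit1 and Cxcl10 between 25HC and GW3965 ended when 1 library was left out, in 10, 7 and 7 fits, with adjusted p up to 0.131 (Mmp3, without 25HC replicate 5). Without the 4 libraries, none of which is in the 25HC or GW3965 group, the counts were 870 higher and 804 lower with 25HC and 1096 higher and 1182 lower with 25HC3S, and all 222 and all 591 called genes were called again. There 11 and 12 of the LXR target genes, all 19 of the cholesterol biosynthesis enzymes and 16 of the 17 fatty acid genes were lower with 25HC and with 25HC3S, and all 20 proliferation genes were higher with each. Rescaling the values to TPM moved the share of higher calls in these comparisons from 51.4% to 58.1% and from 45.9% to 53%.

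The 3 comparisons with Vehicle share their control libraries. Across the 12752 genes, which are not independent replicates, the log2 differences of 25HC and 25HC3S had r = 0.77, those of 25HC and GW3965 r = 0.84 and those of 25HC3S and GW3965 r = 0.67. Unchanged groups simulated against the same controls gave medians of 0.77, 0.84 and 0.74 over 100 sets. The covariances were 0.0583, 0.0829 and 0.0560, against simulated means of 0.0331, 0.0328 and 0.0330 with SDs of 0.029, 0.028 and 0.029. With Vehicle replicates 1 and 2 as the control of the first compound and 3 to 5 as that of the second, r was 0.10, 0.13 and -0.24, and with the parts exchanged -0.27, 0.04 and 0.02. Of called genes, 17 were higher and 29 lower in both 25HC3S and GW3965, 25 moved in opposite directions, and independent lists of those sizes would share 2.06 and 4.34. All 4 genes higher with 25HC were also higher with GW3965, with 0.14 given by independent lists, and Abca1 moved oppositely. Between 25HC and 25HC3S 0 genes were called in the same direction and 3, Sqle and Srebf2 among them, in opposite directions. Simulated unchanged groups reached up to 2830 shared calls in one direction in a single set, and as many called genes as the real count in 27 of the 100 sets for 25HC with Vehicle, 14 for 25HC3S with Vehicle and 7 for GW3965 with Vehicle. Their libraries were drawn with replacement, so a simulated group can hold a library more than once, unlike the real groups. These counts need not be those of real unchanged groups.

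Markers of other cells gave few calls with all 20 libraries. Of the erythroid and neutrophil list 0 of 11 members passed the filter on low values. Of 9 endothelial and 9 skeletal muscle markers 3 each were measured, and 0 were called against Vehicle; Acta1, a muscle actin, was lower with 25HC3S than with GW3965 by -0.83, a call that ended without 25HC3S replicate 3 or 4 or GW3965 replicate 3 or 4 (adjusted p up to 0.065). Of 5 adipocyte markers 0 were called against Vehicle and Adipoq was lower with 25HC3S than with 25HC by -0.89, a call that ended in 8 of the 10 fits that leave out 1 library of the pair (adjusted p up to 0.135, without 25HC replicate 3). Between these groups the list's median was -0.59, with 3 lower adjusted over the list alone (adjusted p = 0.0018, then adjusted p = 0.07 with an estimated correlation). Against GW3965, 1 of the 5 was lower with 25HC3S (median -0.46, adjusted p = 0.08 for the list). With 25HC3S against Vehicle 2 of the 5 adipocyte markers fell without the 4 libraries, where the median went from -0.21 to -0.47 (adjusted p = 0.16 with an estimated correlation). Of 4 osteoblast and osteocyte and 7 synovial lining and tendon markers 0 were called in any comparison with all 20 libraries. With the 4 left out, 1 osteoblast and osteocyte marker was lower in 25HC3S than in 25HC, and 1 was higher with each oxysterol than with GW3965. The synovial and tendon list had medians of 0.34, 0.00 and 0.04 against Vehicle with no call, and Vehicle replicates 3 and 4 lay at -0.95 and -0.94 for it relative to Vehicle replicates 1 and 5. Between 25HC3S and 25HC this list was called lower, with 7 of 7 members negative and 0 called (median -0.27, adjusted p = 0.001, and 0.042 with an estimated correlation). Leaving the 4 libraries out, 2 of the 7 fell with 25HC3S against Vehicle (median -0.23, adjusted p = 0.0095 with an estimated correlation) and 2 with GW3965 (median -0.06, 0.049 with an estimated correlation), 1 was lower in 25HC3S than in 25HC, 3 were higher with 25HC than with GW3965, and 3 were lower and 1 higher with 25HC3S than with GW3965. Of the lists not yet given, the unfolded protein response (medians -0.09, -0.02 and -0.08 for 25HC, 25HC3S and GW3965 against Vehicle) and Hedgehog target genes (0.16, 0.03 and -0.05) had 0 called members and no list call against Vehicle with all 20 libraries.

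The main genes named lie, on build GRCm38, as follows: Sqle (ENSMUSG00000022351) on chromosome 15 from 59315077 to 59331192, Srebf2 (ENSMUSG00000022463) on chromosome 15 from 82147181 to 82205379, Abca1 (ENSMUSG00000015243) on chromosome 4 from 53030787 to 53159895, Abcg1 (ENSMUSG00000024030) on chromosome 17 from 31057698 to 31115777, and Srebf1 (ENSMUSG00000020538) on chromosome 11 from 60199089 to 60222581. Mrc1 (ENSMUSG00000026712) lies on chromosome 2 from 14229392 to 14332057. Mmp12 (ENSMUSG00000049723) lies on chromosome 9 from 7344381 to 7369499, near Mmp3 (ENSMUSG00000043613), from 7445822 to 7455975, and Mmp13 (ENSMUSG00000050578), from 7272514 to 7283331. The FPKM of each is over its whole annotated gene model.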

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

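The tests of random loss and of held-out pairs, the count of called genes in simulated groups, the tests of the low-complexity Vehicle libraries, of exchanged libraries or labels and of the macrophage markers were chosen after the result was seen, and those of depth, of gene length and GC content and of other splits of the libraries before.

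In each group of 5 libraries, the highest or lowest value was set against its gap to the next, and 21 of 272 checks stood out, where chance marks about 1 in 20 groups. Of these, 9 were in 25HC3S replicate 1, one of the 4 libraries with few genes at exactly 1 fragment (1171, against 1842 to 2049 in its group, with 3.14% of fragments in mitochondrial genes against 1.34% to 1.41%). It had 55.2 FPKM of Scd1, 10.3 of Ifit1, 31.3 of Acly, 18.4 of Srebf1, 19.8 of Adamts5, 18.7 of Slfn9 and 8.85 of Ncapg2. In Vehicle, replicate 3 had 20.5 FPKM of Insig1, 18.5 of Postn and 16.8 of Mcm4, replicate 4 had 19 of Car3 and replicate 2 had 9.15 of Lpcat3. A gap to the next value misses libraries of a group that stand apart together. Mki67 in Vehicle replicates 3 and 4 (43.0 and 42.9 FPKM) did not stand out by it, so the number of checks that stood out does not rank the groups. In 25HC, replicate 2 had 5.69 FPKM of Ifit1 and replicate 4 had 0.888% of fragments in mitochondrial genes. In 25HC3S, replicate 2 had 2.89 FPKM of Fdft1 and replicate 5 had 245 of Lum. In GW3965, replicate 3 had 11.9 FPKM of Ucp2, and replicate 5 had 4.46 of Vcam1 and 68.3 of Cdkn1a.

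Several genes were called in opposite directions against Vehicle by a pair of compounds, and the direct difference of each pair is given here. It follows from the selection, being the one difference minus the other, and is no further evidence. Between 25HC3S and 25HC the log2 difference was -1.15 for Sqle and -0.65 for Srebf2. Between 25HC and GW3965 it was -4.01 for Abca1. Between 25HC3S and GW3965 it was -1.59 for Sqle, -0.99 for Srebf2, -1.73 for Msmo1, -2.80 for Insig1, -1.82 for Cyp51, -1.56 for Hmgcs1, -1.45 for Lss and -1.57 for Fdft1. For genes of fatty acid metabolism it was -3.44 for Scd1, -1.81 for Acsl3, -2.79 for Fads2 and -0.93 for Acly, and for Ckap2 it was 0.90.

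In 4 libraries few genes had exactly 1 fragment. Lower depth is argued against, since the other 16 libraries, thinned to the depth of the shallowest library (14653777 fragments), kept at least 1891 such genes. Random loss of molecules alone is argued against for Vehicle replicates 3 and 4 and 25HC3S replicate 1, whose deviations from the other libraries had r of at least 0.86 across 4279 genes, which are not independent replicates. For comparison, Vehicle replicate 2 had r of 0.13 to 0.14 with the 3, and pairs of the other 16, each held out of its reference, had a median of 0.03 and at most 0.80, or at most 0.55 for 2 libraries of different groups, while the 3 span 2 groups. The deviations of Vehicle replicate 3 followed gene length (Spearman correlation 0.42) and GC content (-0.62). A trend on gene length and GC content is argued against as the whole cause, though not as a part of it, since r stayed at 0.77 or more after its removal, against at most 0.81 for the held-out pairs and at most 0.55 for those of different groups. What these 3 libraries share beyond that stays open, and no biological explanation was tested.

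Cholesterol synthesis genes tended higher, and Abca1 was lower, in 25HC than in Vehicle, the reverse of the textbook action of an oxysterol. Of the 19 enzymes 17 had a positive difference but 1 was called, and the list's adjusted p was 0.15 with an estimated correlation. The low-complexity Vehicle libraries are argued against as the whole cause. Without the 4 libraries the median of the enzymes was 0.27, with 18 of 19 positive. Its SE of 0.04 is over members, which are not independent replicates, so it leaves out the spread between libraries. The 2 Vehicle libraries left had mean log2 levels of 27 sterol genes of 3.11 and 3.18, below the lowest 25HC library at 3.31. The fit rests on these 2, so chance between Vehicle libraries is not excluded. Abca1 was still lower in that fit, at -0.46 ± 0.06 (SE). That is smaller than its -0.79 with all 20, so these libraries carry part of the Abca1 difference. A swap of single libraries between the groups is argued against, since 0 libraries lay inside the other group's range of the mean log2 level of 27 sterol genes (3.31 to 3.44 in 25HC, 2.99 to 3.18 in Vehicle). An exchange of both groups' labels as a whole cannot be told apart from an action of 25HC in these cells, since the Abca1 difference, negative in both fits, would have this sign in either case and no measure outside expression identifies the groups.

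Macrophage markers changed in both directions with 25HC3S. Fewer macrophages in the cultures are argued against as the sole cause, since without the 4 libraries the 95% intervals of 6 of 14 markers left out the list's median of -0.63, among them Cd14 at 0.74, Mrc1 at -1.65 and Ptprc at -0.03. This holds only if the mRNA of the markers came from macrophages alone, which was not tested. Falls of genes with low values are also understated on the log2(FPKM + 1) scale. The low-complexity libraries are argued against as the whole cause, since without them 8 of the markers were called lower, against 2 with all 20, and Cd14 was still higher, at 0.74. A change of state of the macrophages in the cultures, or a change in number together with one of state, stays open as an untested hypothesis, and a source of these mRNAs in other cells was not examined.

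Other splits of the same 10 libraries, 100 of 126 drawn, were used to ask whether chance could give as many called genes. By the splits it is argued against for 25HC3S with 25HC (104 genes, at most 1 in another split), 25HC with GW3965 (222, at most 1) and 25HC3S with GW3965 (591, at most 1). In each of these, 1 split, the real one, reached the real count. Unchanged groups, simulated from the same libraries drawn with replacement, reached it in 1, 0 and 1 of 100 sets, with up to 118, 17 and 606 genes. A simulated group can hold the same library more than once, which no real group does. The counts of the simulated sets, here and below, need not be those of real unchanged groups. Both tests take the 5 libraries of a group as independent, which the labels do not state, so chance between animals or cultures is not excluded. For 25HC with Vehicle (5 genes) and GW3965 with Vehicle (824), too, another split gave at most 1 gene and 1 split, the real one, reached the count, but the simulated unchanged groups reached it in 27 and 7 of 100 sets, with up to 5792 and 6339 genes. So the number of called genes in these 2 comparisons does not by itself exclude chance in which Vehicle libraries were drawn. It cannot be excluded for 25HC3S with Vehicle, where 19 splits, the real one among them, called at least the real 205 genes, and 14 of 100 simulated sets did. The highest split called 5731 and set Vehicle replicates 2, 3 and 4 and 25HC3S replicates 1 and 5 against the rest. All 4 libraries with few genes at exactly 1 fragment lay on the same side there, which points to a structure of the samples.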

How the results depend on the processing

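Leaving out the 4 libraries of low complexity was chosen after seeing the data, and the other alternatives before. Counts of called genes stayed within 1.5 times the reported count in every comparison with a pseudocount of 0.1, TPM, median-of-ratios scaling, no trend or a robust trend in the spread, and voom on the recovered fragments. Where another count is given below the cause was not tested, except that filters change the genes tested and smaller sets hold fewer libraries. For 25HC with GW3965, whose groups hold none of the 4 libraries, leaving these out changes only the shared estimate of the spread. The Abca1 difference there stayed at -4.01 while its SE went from 0.13 to 0.05. Depth of 14653777 to 19365220 fragments limits genes near the filter on low values.

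With no filter, 0 genes were lower in 25HC than Vehicle and 13 higher in 25HC3S than 25HC. With FPKM of at least 5 in 5 libraries, 95 genes were lower in 25HC3S than Vehicle, 209 lower in GW3965 than Vehicle, 12 higher in 25HC3S than 25HC, 64 higher in 25HC than GW3965, and 120 higher and 210 lower in 25HC3S than GW3965. With only the 2 groups compared, 49 calls of named genes over the 6 comparisons ended, with the same direction, and 2 were gained. A call named in the results may therefore not hold in a fit of its 2 groups alone. The counts higher and lower in that fit were 1 and 0 for 25HC with Vehicle, 6 and 17 for 25HC3S with Vehicle, 84 and 68 for GW3965 with Vehicle, 32 and 173 for 25HC3S with 25HC, 749 and 678 for 25HC with GW3965, and 439 and 570 for 25HC3S with GW3965. With library weights they were, in the same order, 12 and 4, 283 and 486, 619 (lower only), 362 and 691, 890 and 786, and 1136 and 1236. With the replicate block, 1 gene was higher and 0 lower in 25HC than Vehicle, 36 higher in 25HC3S than Vehicle, 278 higher in GW3965 than Vehicle and 11 higher in 25HC3S than 25HC; the numbers do not pair the libraries. Without the 4 libraries, 2 genes were higher in 25HC than Vehicle, and the counts higher and lower were 169 and 335 for 25HC3S with Vehicle, 317 and 599 for 25HC3S with 25HC, 870 and 804 for 25HC with GW3965, and 1096 and 1182 for 25HC3S with GW3965.

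The values given here turned direction and were called in the alternative fit, and none had been called with all 20 libraries. Others turned without a call in either fit. Without the 4 libraries these included Abca1 (-0.21 to 0.01) and Srebf1 (0.04 to -0.17) in 25HC3S with Vehicle and Adamts5 (-0.33 to 0.03) in 25HC with Vehicle. Adamts5 in GW3965 with Vehicle went from -0.05 to 0.28 with library weights (adjusted p = 0.0217) and 0.31 without the 4 libraries (adjusted p = 0.0195). Without the 4 libraries, list medians for 25HC with Vehicle became 0.08 for fatty acid synthesis, -0.08 for inflammatory mediators, -0.20 for interferon-stimulated genes, 0.06 for the unfolded protein response and -0.07 for macrophage markers. The median became -0.05 for lysosome and autophagy in 25HC3S with Vehicle and -0.06 for synovial and tendon markers in GW3965 with Vehicle.

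With Vehicle replicates 1 and 2 for the first compound and 3 to 5 for the second, r across genes was 0.10 (25HC and 25HC3S), 0.13 (25HC and GW3965) and -0.24 (25HC3S and GW3965), and with the parts exchanged -0.27, 0.04 and 0.02. In the first split 0 genes were higher in both 25HC and GW3965, 2 in both 25HC3S and GW3965, and 11 lower in both of the latter. In the exchanged split 1 gene was higher and 7 lower in 25HC and 25HC3S, 35 higher and 23 lower in 25HC and GW3965, and 10 higher and 9 lower in 25HC3S and GW3965.

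With 1 library left out at a time, higher counts for 25HC with Vehicle ran from 1 (without 25HC replicate 3) to 1445 (without Vehicle replicate 1) and lower from 0 (without Vehicle replicate 2, among others) to 1214 (without Vehicle replicate 1). For 25HC3S with Vehicle they ran from 23 (without 25HC3S replicate 3) to 339 and from 74 (without 25HC3S replicate 2) to 283, and for GW3965 with Vehicle from 233 (without GW3965 replicate 1) to 1820 and from 216 (without GW3965 replicate 2) to 1427, each highest without Vehicle replicate 1. For 25HC3S with 25HC they ran from 5 (without 25HC replicate 4) to 11 (without 25HC replicate 5) and from 54 (without 25HC replicate 3) to 84 (without 25HC replicate 2). For 25HC with GW3965 they ran from 69 (without 25HC replicate 3) to 95 (without 25HC replicate 2) and from 82 (without GW3965 replicate 4) to 90 (without GW3965 replicate 1). For 25HC3S with GW3965 they ran from 203 (without GW3965 replicate 1) to 248 and from 233 (without GW3965 replicate 3) to 278, both highest without 25HC3S replicate 1.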

Other observations

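The lists and their tests were chosen before the result was seen, and the genes named are list members with the smallest p in the comparison.

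Some lists not described so far for these comparisons differed between an oxysterol and GW3965, given at 20 µM and 2 µM. Of 11 PPAR target genes 4 were lower with 25HC3S than with GW3965 (7 adjusted over the list alone), Plin2 of the lipid droplet coat by -0.89 among them, and the list's median was -0.37 (adjusted p = 4.7e-07, and 0.00018 with an estimated correlation). With 25HC 1 of the 11 was lower than with GW3965, Plin2 by -0.50 (adjusted p = 0.00031 for the list, and 0.0036 with an estimated correlation). Of 12 p53 target genes 2 were lower with 25HC3S than with GW3965, Sesn1 by -0.52 and Cdkn1a by -0.36, the latter call ending in 9 of the 10 fits without 1 library of the pair, all but that without 25HC3S replicate 4, with adjusted p up to 0.14 without 25HC3S replicate 1 (adjusted p = 0.0015, and 0.017 with an estimated correlation), and 0 with 25HC (adjusted p = 0.0062, and 0.041 with an estimated correlation, which became adjusted p = 0.057 without the 4 libraries of low complexity). Of 14 dedifferentiation and fibroblast genes Postn (-0.56) and Acta2 (-0.77), a smooth muscle actin, were lower with 25HC3S than with GW3965 (adjusted p = 0.0015, and 0.0081 with an estimated correlation).

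Of 14 macrophage markers 4 were lower and 1 higher with 25HC3S than with GW3965, Mrc1 by -0.91, Adgre1 by -0.50 and Cd14 by 0.77 among them (median -0.63, adjusted p = 9.9e-06, then adjusted p = 0.14 with an estimated correlation). With 25HC, Mrc1 was higher than with GW3965 by 0.61, and by 0.54 without 25HC replicate 5 (adjusted p = 0.0516). Against Vehicle, 25HC3S gave lists with 0 called members and a call lost with an estimated correlation: inflammatory mediators (median 0.29, adjusted p = 0.021, then adjusted p = 0.37), proliferation (0.13, adjusted p = 0.021, then adjusted p = 0.34) and PPAR target genes (-0.13, adjusted p = 0.04, then adjusted p = 0.13). Without the 4 libraries of low complexity the median of the inflammatory mediators was 0.05 (adjusted p = 0.94), and Vehicle replicates 3 and 4 lay at -0.69 and -0.57 for them relative to Vehicle replicates 1 and 5. The medians of the other 2 lists were 0.11 and -0.17 there, with 2 proliferation genes higher (adjusted p = 0.41 with an estimated correlation) and 2 PPAR target genes lower (adjusted p = 0.031 with an estimated correlation).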
